A study of Mus musculus with 2 samples.

How the data were processed

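Total RNA longer than 200 nt was sequenced from the embryonic facial prominence of the mouse strain B6NCrl at embryonic day 10.5. The series held 1 group of 2 biological replicates. Per the labels, replicate 1 was a pool of tissue from 69 embryos and replicate 2 a pool from 51 embryos, with male and female embryos pooled in each. Each library was made from 10 ng of RNA extracted with the mirVana kit, with spike-in RNA controls added, and the labels linked the manual of a SMARTer ultra low input kit. Whether the counting used the strand of the reads was not given in the sources used here, so reads of a gene and of an overlapping antisense gene may be mixed.

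Expected counts per gene were deposited for each library as estimated by the authors, together with posterior mean counts, and were not normalized. TPM values were deposited per gene and per transcript, scaled by the authors to the same total in each file over all of its features, spike-in controls included. The share of each transcript within its gene was deposited by the authors as a percent, from both the maximum likelihood and the posterior mean estimate. Effective lengths in bases were deposited per gene and equalled the transcript length minus 99. Per the file headers and the accompanying notes, reads were placed on the mm10 assembly and quantified against the GENCODE M4 annotation, and the replicates were not pooled with each other. The aligner, the quantifier and their versions were not given in the sources used here.

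Each gene table held 69691 features. Of these, 43346 were Ensembl genes, 96 were spike-in controls, 1 was the phiX genome and 26248 were short entries with numeric identifiers, which were left out of the library sizes and of every comparison. Symbols, gene classes and coordinates were taken by gene identifier, without its version, from GENCODE M21 on GRCm38, the assembly also called mm10. A symbol was found for 42462 genes. The 884 genes without one held 0.255% of the gene counts of replicate 1 and 0.26% of those of replicate 2 and were not named. Expected counts over all features came to 41492881 in replicate 1 and 41153413 in replicate 2, of which genes held 40059176 and 39531700. A chi-square comparison of the libraries over 17546 genes gave 8.94 per degree of freedom, so the libraries differed by more than sampling noise and were counted as 2 samples.

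With 1 group there was no contrast to test, and every result describes these 2 libraries. A gene was called detected at a TPM of at least 1 in both. Replicate correlation was computed across genes with a mean TPM of at least 1 on log2(TPM + 1). The biological coefficient of variation was estimated with edgeR 4.0.16 from expected counts rounded to whole numbers, for genes with a mean count of at least 10, with TMM factors and an intercept as the only term. Genes differing between the replicates were those at least 2-fold apart after TMM scaling with a mean count of at least 50, using a prior count of 2 per library. An exact two-sided binomial test on the reads, with Benjamini-Hochberg adjustment at 0.05, was set beside them. It compares 2 libraries and no condition.

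A set of 33 gene lists holding 470 distinct genes, 39 gene pairs and a panel of 26 genes for isoforms were fixed before the data were examined, as were the tests and all alternatives except those named at the end. The level of a list was the median over its members of the mean TPM, with its percentile among 10000 random lists of protein coding genes of the same size. Those lists were drawn from all named protein coding genes, detected or not. The replicate difference of a list was the median log2 ratio of replicate 2 over replicate 1, set against 10000 random lists of the same size matched on mean expression in 20 bins. A list was called outside when its median lay beyond the central 95% of those lists. Gene pairs were compared on log2(TPM + 0.1), with a standard error from the replicate SD pooled over the 200 genes nearest in level and a 95% interval of 1.96 standard errors. A pair was said to differ by more than the replicate spread when the interval left out 0 and both libraries had the same sign. That spread is the pooled one of genes of like level and not the pair's own. It leaves out errors of TPM that differ from gene to gene. Isoform agreement was the share of genes with a mean TPM of at least 5 and at least 2 annotated transcripts whose most abundant transcript was the same in both libraries. Shares of counts carry exact Clopper-Pearson 95% intervals.

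The genes named in the text followed a fixed rule. It took up to 4 members of highest mean TPM of each list and up to 2 of the lowest, the 15 highest protein coding genes outside the mitochondrial genome and the 5 highest other genes. It also took the 10 largest ratios in each direction, both genes of each pair, the isoform panel, and every list member at least 2-fold apart. Results of 2 genes that this rule took are not reported here, and the counts over all pairs and list members include them. Hbb-bt, Lum, Rarb, Sall4 and Shh in the results, and Afp, Nkx2-5 and the members of second lists in the closing observations, fell outside the rule and were chosen after their values were seen. The sums over adult globin copies were also added after seeing the data.

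The calls of genes and lists, the pooled error of single genes and the coefficient of variation were tested on simulated data. These were drawn from the means and library sizes of the real genes. The pair calls and the other steps were not tested. For genes differing between replicates, over 14105 genes, 66 of 67 genes changed 3-fold and 66 of 66 changed 5-fold were called, 0 of 67 changed 1.5-fold were called, and 2 of 13905 unchanged genes were called. For list differences, over 23819 genes, 11 of 200 random lists (5.5%) and 50 of 50 lists shifted 1.5-fold fell outside. For the pooled error that the pairs use, 981 of 1000 unchanged genes (98.1%) had a difference between the libraries within 1.96 pooled errors. All simulated genes had the same spread, so genes with a larger spread of their own were not covered. For the coefficient of variation, over 17581 genes, a value of 0.1 was recovered as 0.1 from the unchanged genes alone and as 0.137 with 200 changed genes included.

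The alternatives fixed in advance changed the TPM minimum, the pseudocounts, the count filters, the scaling (DESeq2 1.42.0 size factors, total count or spike-in controls), the dispersion estimate, the posterior mean values, the rescaling of TPM over protein coding genes, the prior count and the use of both replicates. Protein coding genes alone and a minimum effective length of 100 bases were added after seeing the data, as were the list medians with spike-in scaling taken without random lists. For the closing observations, 8 second lists of genes were written down before their values were looked at: hindbrain, forebrain and midbrain, heart, muscle differentiation, epidermal differentiation, connective tissue, glycolysis and Y-linked genes. The test of library noise was set after the result had been seen. It replaced an earlier version that compared list members already called 2-fold apart with the spike-in controls, which was dropped because those members had been picked for their ratios. Ratios were also corrected for GC content and length by subtracting the median of genes of like GC content and like length. The computations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.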

Results

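The facial prominence is the tissue of the embryonic face, in which mesenchyme derived largely from the neural crest lies under surface ectoderm. RNA abundance was measured by total RNA-seq in 2 pools of B6NCrl mouse embryos at embryonic day 10.5, replicate 1 from 69 embryos and replicate 2 from 51. Genes received 40059176 expected counts in replicate 1 and 39531700 in replicate 2. The labels named no treatment, no control and no second tissue, so the values describe which genes this tissue expressed and how far the 2 pools differed. Levels are given as mean TPM ± SD with n = 2 pools. Intervals on shares and limits set by counts cover counting error only.

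Outside the mitochondrial genome, actin, globin and histone genes were among the most abundant in the facial prominence. Actb, the cytoplasmic beta-actin gene (ENSMUSG00000029580, chromosome 5, 142903115 to 142906754), led the protein coding genes at 6218 ± 376 TPM. The embryonic beta-like globin Hbb-y (ENSMUSG00000052187, chromosome 7, 103851749 to 103853216) followed at 5398 ± 617 TPM. The other genes of this group were Hist1h2ap (5264 ± 26.7), Ppia (5211 ± 1.03), Ftl1 (4715 ± 199), Eef1a1 (3230 ± 78.6), Hspa8 (3216 ± 170), Eno1 (3156 ± 314), Rpl41 (2965 ± 18.2), Ubb (2935 ± 65.1), Hba-a2 (2900 ± 421), Mif (2899 ± 143), Ptma (2872 ± 162), Tmsb10 (2780 ± 188) and H2afz (2749 ± 5.76). Hist1h2ap has near-identical copies, as do Hba-a2 and Hbb-bs, and the levels of all of them are uncertain. Among other classes, the unprocessed pseudogene Gm28437 stood at 5060 ± 254 TPM, the processed pseudogene Gm10123 at 4382 ± 24.3 and the 7S RNA genes Rn7s2 and Rn7s1 at 4130 ± 0.17 and 4130 ± 0.304. These share sequence with other genes or with each other, so their counts may be split among copies. Gm22133, a microRNA gene of 4778 ± 165 TPM, lay within Ftl1 and had an effective length of only 10 bases, which makes its TPM uncertain.

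Of 42462 named genes, 14090 (33.2%) were detected at a TPM of at least 1 in both pools. Among 21474 protein coding genes the number was 12494 (58.2%), and their median level was 20.1 TPM. Of these, 8384 reached 10 TPM, 1683 reached 100 TPM and 89 reached 1000 TPM. The detected genes also included 480 processed pseudogenes, 268 antisense genes and 220 lincRNAs. Protein coding genes held 96.4% of gene counts in both libraries. A further 635 genes reached a TPM of 1 in replicate 1 alone and 458 in replicate 2 alone.

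Nearly all listed regulators of the facial mesenchyme were detected, and mean levels of the list ran from 1.08 to 292 TPM. The homeobox gene Msx1 (ENSMUSG00000048450, chromosome 5, 37820485 to 37824583) stood at 292 ± 15.1 TPM, Prrx1 at 107 ± 1.08, the chondrogenic regulator Sox9 at 92.5 ± 3.18 and Prrx2 at 77.0 ± 3.57. Of the 25 mesenchyme regulators, 24 were detected, and the list median of 29.1 TPM lay at percentile 99.8 of random protein coding lists. Those lists were drawn from all protein coding genes, of which 58.2% were detected, and their median was 3.5 TPM. Among the detected protein coding genes alone the median was 20.1 TPM. The lowest members were Foxc1 at 4.61 ± 0.735 TPM and the osteoblast regulator Runx2 at 1.08 ± 0.905. Runx2 was the undetected member, with 1.72 TPM in replicate 1 and 0.44 in replicate 2.

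The regional patterning genes of the face were detected throughout. Dlx5, a homeobox gene of the ventral pharyngeal arches (ENSMUSG00000029755, chromosome 6, 6877805 to 6882085), stood at 70.1 ± 10.4 TPM, Dlx1 at 48.7 ± 14.3, Dlx2 at 30.1 ± 3.22 and Dlx3 at 25.7 ± 1.06. All 6 Dlx genes were detected, the lowest being Dlx6 at 4.53 ± 0.629 and Dlx4 at 3.34 ± 0.424 TPM. All 15 frontonasal and maxillary regulators were detected. Their median of 14.4 TPM (percentile 90.2) lay below the median of detected protein coding genes, 20.1 TPM. The list was led by Alx1 (63.3 ± 21.9), Nr2f2 (53.9 ± 4.17), Lhx8 (51.6 ± 2.74) and Nr2f1 (45.7 ± 2.09), while Tbx22 (3.93 ± 1.19) and Pax7 (1.71 ± 0.679) were lowest. All 12 genes of the endothelin-dependent mandibular program were detected (median 29.1 TPM, percentile 97.8), among them Tbx3 at 44.9 ± 2.53, Barx1 at 42.6 ± 8.88 and Ece1, the endothelin-converting enzyme, at 42.4 ± 4.38. The ligand gene Edn1 was the lowest at 1.41 ± 0.127 TPM and Hand2 stood at 4.10 ± 0.99.

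Hox genes, which pattern the hindbrain and more posterior tissue, were mostly undetected. Of 39 Hox genes, 4 were detected in both pools, namely Hoxa2 (11.2 ± 4.84 TPM), Hoxb2 (9.57 ± 6.57), Hoxd3 (3.58 ± 3.11) and Hoxb1 (3.47 ± 3.45). A further 17 had no expected counts in either library, and 15 had counts but no more than 20 in either. By counting error alone, a count of 0 allows at most 3 counts per library. That limit does not cover reads assigned to an overlapping gene, as for Hoxd4, which lies within Hoxd3. Other lists with most members undetected were the FGF family genes, labeled FGF ligands (7 of 22 detected), the heart genes (2 of 10) and the liver and yolk sac genes (4 of 9). The heart count depended on replicate 1, where Myh7 (0.75 TPM) and Tnnt2 (0.93) fell short, against 3.94 and 3.69 TPM in replicate 2. In the FGF family the detected members were led by Fgf8 (33.9 ± 3.98 TPM), Fgf13 (15.2 ± 1.25), Fgf15 (14 ± 1.5) and Fgf10 (7.0 ± 0.304), and Fgf6 and Fgf21 had no counts. Alb, the albumin gene, had no counts in either library, and Trf, the transferrin gene, reached 19 ± 1.28 TPM.

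Cells other than mesenchyme were represented at graded levels. The facial ectoderm list had 18 of 20 members detected (median 12.3 TPM), with Krt18 at 84.7 ± 3.08, Krt8 at 81.5 ± 3.02, Cldn6 at 62.9 ± 1.47 and Epcam, an epithelial adhesion gene, at 51.6 ± 2.09. Grhl1 was undetected at 0.465 ± 0.177. All 13 genes of neurons and cranial ganglia were detected (median 35.3), led by the neuronal tubulin Tubb3 at 190 ± 2.65, Nefm at 92.5 ± 7.86, Nefl at 84.5 ± 4.74 and Elavl4 at 71.3 ± 5.87. Endothelial genes were all detected (12 of 12, median 18.7), with Egfl7 at 79.8 ± 2.65, Ramp2 at 57.0 ± 0.742, Esam at 23.0 ± 0.262 and Emcn at 21.9 ± 1.17. Macrophage genes were all detected at low levels (12 of 12, median 5.08), with C1qb at 15.6 ± 1.95 and Adgre1 at 1.38 ± 0.325. For olfactory placode genes 14 of 14 were detected (median 11.4), with Eya1 at 41.4 ± 1.06, and for migratory neural crest and glia 8 of 10 (median 14.3), with Sox10 at 10.1 ± 0.912 and Foxd3 at 0.47 ± 0.156. Lower medians were found for skeletal muscle precursors (6 of 11 detected, 3.79 TPM), eye and pigment genes (7 of 10, 2.37), pharyngeal endoderm (7 of 10, 2.00) and neural tube progenitors (5 of 10, 1.82). Fabp7 (107 ± 1.34) and Hes5 (98.6 ± 38.7) were high members of the last list, and En2 (0.025 ± 0.0210) was its lowest. The erythroid list had 13 of 13 members detected, with Hbb-bh1 at 2580 ± 79.0 and Hba-x at 2196 ± 189 TPM.

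**Figure D1:**
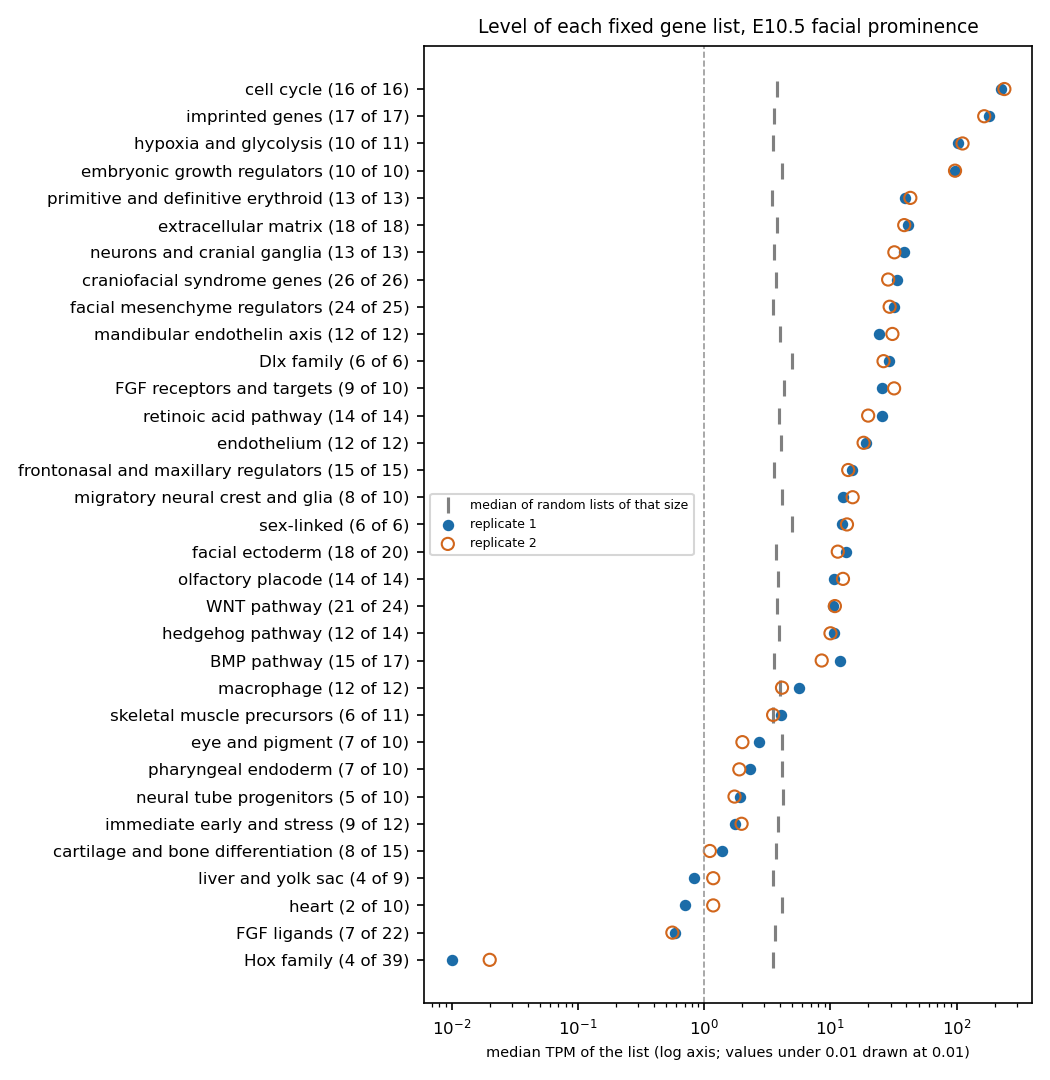
Median TPM over the members of each of 33 gene lists (log axis) in replicate 1 (filled circles) and replicate 2 (open circles), with the number of members detected out of those in the table; grey ticks mark the median of random protein coding lists of the same size. Cell cycle genes sit highest at 226 and 239 TPM and Hox genes lowest at 0.00 and 0.02 TPM.

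Genes of signaling pathways that act in the face were mostly detected. Retinoic acid binding protein genes were the most abundant, Crabp1 at 1219 ± 122 TPM and Crabp2 at 624 ± 62.7, and all 14 genes of the retinoic acid list were detected (median 21.8). In the BMP list 15 of 17 were detected (median 10.2), and the target genes Id3 (506 ± 7.44), Id2 (319 ± 1.58) and Id1 (144 ± 11.3) stood above the ligand Bmp4 (20.1 ± 1.26). The FGF receptors and targets had 9 of 10 members detected (median 27.6), with Dusp6, a feedback phosphatase of FGF signaling, at 103 ± 6.77, Fgfr2 at 67.3 ± 1.45 and Fgfr1 at 56.1 ± 5.92, while Fgfr4 was at 0.395 ± 0.0210. The WNT list had 21 of 24 detected (median 11.3), led by Sfrp2 (134 ± 6.96) and Wls (76.5 ± 0.99). The hedgehog list had 12 of 14 (median 10.3), led by the coreceptor Gas1 (65.7 ± 0.226), with the ligand genes Shh at 2.25 ± 0.594 and Ihh at 0.05 ± 0.0710.

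The cell cycle and imprinted lists stood highest among the lists, followed by hypoxia and glycolysis and then by embryonic growth regulators. The cell cycle list was fully detected (16 of 16, median 233 TPM, percentile 100), with Cdk1 at 450 ± 0.962, Ccnb1 at 349 ± 2.94 and Birc5 at 345 ± 8.62. Imprinted genes were all detected (17 of 17, median 182), led by Mest at 1766 ± 185 and Grb10 at 551 ± 19.6. Embryonic growth regulators were all detected (10 of 10, median 97.5), with Hmga1 at 737 ± 41.4 and Igf2bp2 at 156 ± 12.3. The hypoxia and glycolysis list had 10 of 11 detected (median 107), with Ldha at 2435 ± 295 and Car9, an enzyme gene induced by hypoxia, at 0.825 ± 0.0350. All 26 genes of human craniofacial syndromes were detected (median 31.1, percentile 99.9), led by the splicing gene Snrpb at 774 ± 22.5 and Eftud2 at 295 ± 2.13, with Tbx22 lowest. Extracellular matrix genes were all detected (18 of 18, median 39.9), led by Col3a1 (334 ± 38) and Sparc (257 ± 26.6). Of the cartilage and bone genes 8 of 15 were detected (median 1.25), Col2a1 at 234 ± 3.28 and Col9a1 at 90.9 ± 1.77 being the highest and Dmp1 and Matn1 being at 0.065 ± 0.00700 and 0.05 ± 0.0710. Immediate early and stress genes had 9 of 12 detected (median 1.80), with Ier2 at 121 ± 3.97 and Jun at 62.1 ± 5.34. The 6 sex-linked genes were detected in both pools (median 13.2). In all, 29 of 33 lists had at least 50% of their members detected.

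Within gene families, one member commonly exceeded its relative. Dlx5 exceeded Dlx6 15.2-fold (95% interval 11.8 to 19.4), Msx1 exceeded Msx2 7.10-fold (6.31 to 7.98) and Sox9 exceeded Sox10 9.08-fold (7.53 to 10.9). The embryonic globin Hbb-y exceeded the adult globin Hbb-bs 196-fold (171 to 225), but only 23.6-fold the sum of Hbb-bs and its near-identical copy Hbb-bt (229 ± 109 TPM). These intervals rest on the pooled spread of genes of like level and can be narrower than a pair's own spread. Both libraries lay outside the log2 interval for Msx1 over Msx2 (3.005 and 2.649, interval 2.658 to 2.997) and Hbb-y over Hbb-bs (7.23 and 8.001, interval 7.415 to 7.816). The cadherin of mesenchyme and neural tissue Cdh2 exceeded the epithelial Cdh1 3.91-fold (3.40 to 4.50). The ligand Bmp4 exceeded Bmp2 10.2-fold (5.84 to 18.0), and Pax3 exceeded Pax7 8.30-fold (5.62 to 12.2). In the other direction, Tfap2a was below Tfap2b by a log2 difference of -2.35 (interval -2.68 to -2.01), Hand2 below Hand1 by -2.74 (-3.17 to -2.30), Edn1 below its receptor gene Ednra by -4.23 (-4.85 to -3.60) and Hmga2 below Hmga1 by -3.25 (-3.38 to -3.12).

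Most of the other pairs, many with smaller differences, also differed by more than the pooled replicate spread. The intervals hold replicate spread only. Errors of TPM that differ from gene to gene are left out, so a small difference may not be one of abundance. Twist1 was below Twist2 by -0.75 (-0.96 to -0.54), Dlx2 below Dlx5 by -1.21 and Tfap2a below Tfap2c by -1.11. Fold differences under 2 were found for Prrx1 over Prrx2 (1.39), Dlx1 over Dlx2 (1.58), Esrp1 over Esrp2 (1.65), Crabp1 over Crabp2 (1.95), Lin28b over Lin28a (1.62), Igf2 over H19 (1.25), Ccnd2 over Ccnd1 (1.18), Nr2f2 over Nr2f1 (1.18), Ednra over Ednrb (1.45) and Cyp26b1 over Cyp26c1 (1.85). Larger mean ratios were those of Dlx5 over Dlx3 (2.71), Fgfr2 over Fgfr3 (3.67), Ptch1 over Gli1 (2.08), Gli3 over Gli1 (3.13), Aldh1a3 over Aldh1a2 (7.57), Wnt5a over Wnt5b (2.81), Col3a1 over Col1a1 (5.35) and Dlx2 over Hoxa2 (2.81). Hba-x exceeded Hba-a1 1.44-fold, yet stood at 0.495 of the sum of Hba-a1 and its near-identical copy Hba-a2 (4435 ± 626 TPM). Fgfr1 was below Fgfr2 by -0.27 and Meis2 below Meis1 by -0.23. Bmp4 and Bmp7 differed by 0.24 (-0.03 to 0.50) and Xist and Ddx3y by 0.21 (-0.07 to 0.50), both within the replicate spread. Of the 39 pairs, 37 differed by more than the replicate spread, as pooled over genes of like level. Both libraries lay outside that interval for some of them, such as Ednra over Ednrb (1.016 and 0.046, interval 0.289 to 0.773). An exact permutation test of 2 values against 2 cannot give a two-sided p below 0.33, so none was used. The log2 difference varied most between replicates 1 and 2 for Fgfr2 over Fgfr3 (2.59 and 1.16), Dlx2 over Hoxa2 (2.05 and 0.93) and Aldh1a3 over Aldh1a2 (2.37 and 3.48). In 1 replicate alone 5 calls were lost, since Ednra over Ednrb (0.05) and Nr2f2 over Nr2f1 (0.11) were within the spread in replicate 2 alone, as were Fgfr1 over Fgfr2 (-0.14), Cyp26b1 over Cyp26c1 (0.46) and Meis2 over Meis1 (-0.13) in replicate 1 alone.

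**Figure D2:**
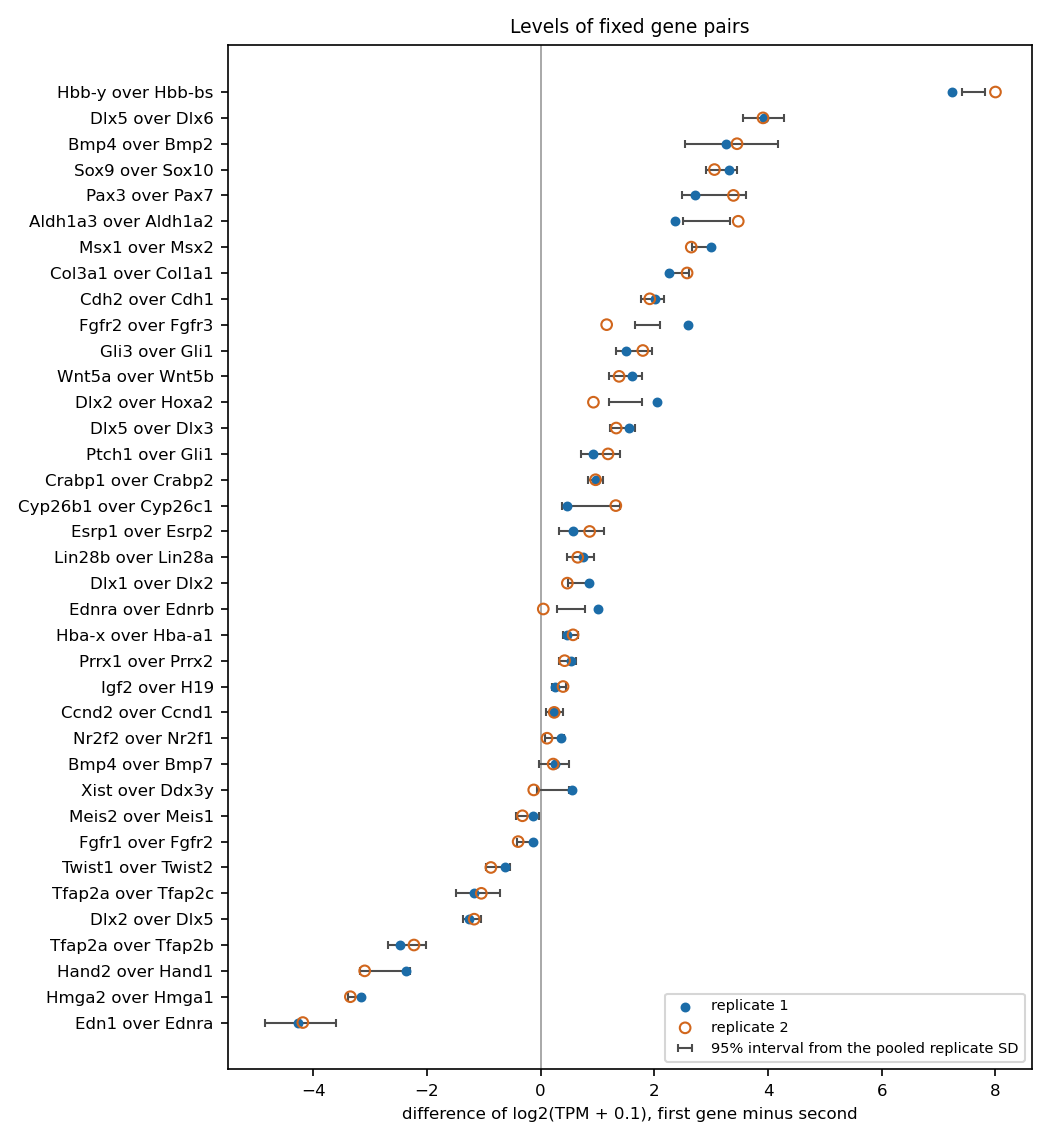
Difference of log2(TPM + 0.1) between the genes of 37 pairs, first gene minus second, in replicate 1 (filled circles) and replicate 2 (open circles), with bars for the 95% interval of the mean from the pooled replicate SD. Hbb-y over Hbb-bs is the largest at 7.62 and Edn1 over Ednra the lowest at -4.23.

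Transcript usage was largely shared between the pools. The most abundant transcript was the same in both libraries for 7276 of 7753 genes, or 93.9% (exact 95% interval 93.3% to 94.4%). In the panel of 26 genes, 24 had at least 2 annotated transcripts, and it was the same for 18 of these. Dlx5-201 made up 92.3% ± 1.58 of Dlx5 transcripts, Msx1-201 95.3% ± 0.37 of Msx1, Tfap2a-201 91.6% ± 3.23 of Tfap2a, Gli3-201 66.9% ± 0.96 of Gli3 and Col2a1-201 62.8% ± 2.13 of Col2a1. The noncoding transcript Meg3-205 made up 70.7% ± 0.88 of Meg3, while Fn1-201 held 52.7% ± 3.44 of Fn1, Fgfr1-202 44.3% ± 0.81 of Fgfr1, Fgfr2-217 28.7% ± 1.22 of Fgfr2 and Prrx1-201 31.1% ± 1.20 of Prrx1. Leading transcripts with less than 50% of their gene were also seen for Vegfa (47.5% ± 3.97), Enah (46.1% ± 2.08), Tcf7l2 (45.4% ± 0.52), Numb (43.2% ± 0.28), Igf2 (39.9% ± 1.57), Tpm1 (35.6% ± 2.54), Ctnnd1 (30.8% ± 4.29) and Meis2 (22.4% ± 7.6). The other panel genes, Twist1 and Ptbp2, had 1 annotated transcript each. A different transcript led in each library for 6 panel genes, Fgfr3, Pax6, Meis1, Cd44, Ptbp1 and H19. For Fgfr3, transcript Fgfr3-201 rated 25.2% in replicate 1 and 49.0% in replicate 2, and for Pax6, transcript ENSMUST00000111087 rated 31.2% and 7.25%.

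The pools were alike for most genes. Across 14759 genes Pearson's r was 0.988 and Spearman's rho 0.989, computed across genes, which are not independent replicates, and the median absolute log2 ratio was 0.10. The biological coefficient of variation was 0.101 over 17567 genes. Spike-in controls took 3.46% of counts in replicate 1 (3.45% to 3.46%) and 3.94% in replicate 2 (3.94% to 3.95%), a mean of 3.70% ± 0.344. Mitochondrial genes took 0.957% and 0.866%, ribosomal protein genes 2.56% and 2.58%, replication-dependent histone genes 0.205% and 0.20%, and the 10 most abundant genes of each library 3.54% and 3.63%.

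Hox, neural tube and heart genes were higher in replicate 2, while extracellular matrix genes were higher in replicate 1. The facial ectoderm and skeletal muscle lists, with 2-fold members higher in replicate 1, lay within the range of random lists (medians -0.07 and -0.17), and the muscle list also held Actc1, 2-fold higher in replicate 2. Hoxb1, a hindbrain segment gene (ENSMUSG00000018973, chromosome 11, 96365752 to 96368256), was 5.83-fold higher in replicate 2, with 1.03 TPM in replicate 1 and 5.91 in replicate 2 (47.0 and 277 counts; adjusted p = 4.4e-40 by the exact binomial test on reads, which compares these libraries only). Dbx1, a gene of neural tube progenitors (ENSMUSG00000030507, chromosome 7, 49631499 to 49636849), was 4.28-fold higher, and Myh7, a cardiac myosin gene (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626), 5.25-fold higher. In the other direction, replicate 1 had 4.50-fold more of Krt5, a basal keratin gene (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898), 4.65-fold more of the muscle regulator Myog and 2.45-fold more of the matrix gene Tnc. Each side was 1 library, so these differences had no replicate check.

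Of 14118 genes tested, 79 were at least 2-fold higher and 97 at least 2-fold lower in replicate 2, together 1.25%, and 95.4% lay within 1.5-fold. Scaling to the spike-in controls instead gave 49 higher and 187 lower, that is 20.8% higher against 44.9%, because it moved the median log2 ratio of all genes to -0.21. The exact binomial test on reads called 4292 genes. It takes reads as independent and covers counting error only, and nearly any 2-fold gene at these counts passes it. By class, the 176 genes 2-fold apart were 156 protein coding genes, 9 processed pseudogenes, 4 antisense genes, 3 lincRNAs, 1 processed transcript, 1 gene to be experimentally checked and 2 without a class.

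The largest ratios included several uncertain genes. The processed pseudogenes Gm4294 and Gm5537 had 0 counts in replicate 1 and 528 and 130 in replicate 2, at least 180.5-fold and 44.6-fold higher against a floor of 3 counts per library. For Rpl21-ps15 the reverse held, with at least 33.5-fold more in replicate 1. The posterior mean counts of these genes were far closer, 1754 in replicate 1 and 2280 in replicate 2 for Gm4294, 72.6 and 279 for Gm5537, and 152 and 51.8 for Rpl21-ps15, so the bounds hold for the expected counts only. Gm14434 (log2 ratio -4.56), Zfp965 (-3.49) and Gm3055 (-3.48) have close relatives, and mt-Nd4l (-1.99) is a short mitochondrial gene. With posterior mean counts Gm4294, Zfp965 and mt-Nd4l were under 2-fold apart. The other genes at this end were the neural tube genes Dbx2 (9.84-fold higher in replicate 2) and Foxb1 (7.65-fold), Scube2 (6.97-fold), Slc18a3, the vesicular acetylcholine transporter (4.59-fold), and the serotonin receptor gene Htr3a (4.56-fold). Col17a1, a hemidesmosome collagen, Pirt and Hic1 were 5.30-fold, 5.29-fold and 5.25-fold higher in replicate 1.

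**Figure D3:**
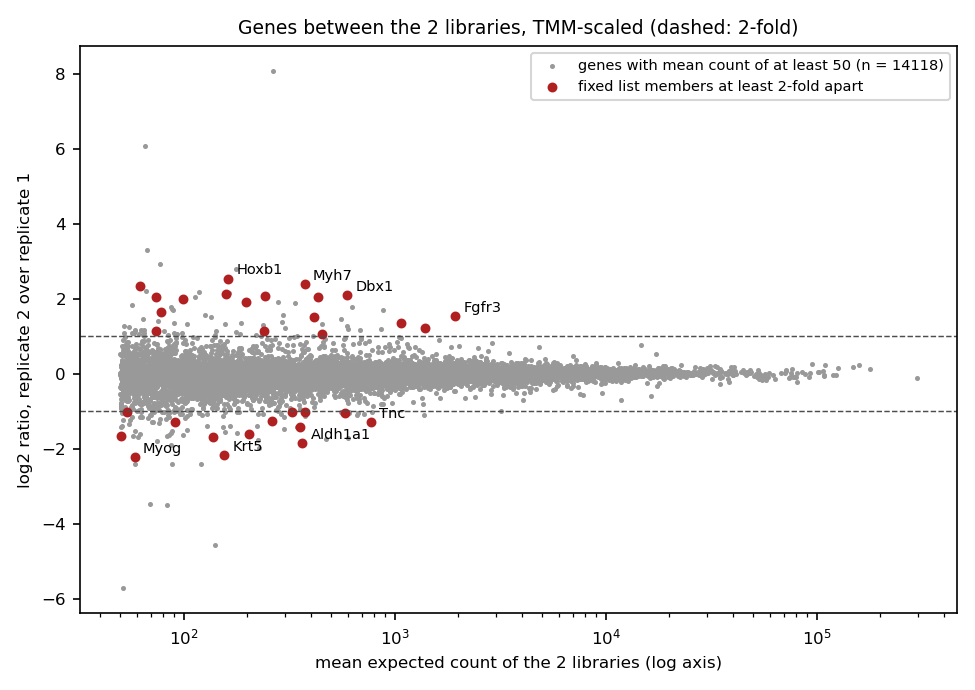
Log2 ratio of TMM-scaled counts, replicate 2 over replicate 1, against the mean expected count (log axis) of 14118 genes, with dashed lines at 2-fold and red points for the 32 list members at least 2-fold apart. Hoxb1 lies at 2.54 and Myog at -2.22.

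Members of the fixed lists made up 32 of the 2-fold genes, 18 higher and 14 lower in replicate 2. The higher ones included the Hox genes Hoxb1, Hoxd3 (4.21-fold), Hoxb3 (3.99), Hoxa3 (3.15) and Hoxb2 (2.87), the neural genes Dbx1, Wnt7a (3.77), Neurog2 (2.21) and Wnt3a (2.20), and the sarcomere genes Myh7, Myh6 (5.12), Myl7 (4.38), Tnnt2 (4.13) and Actc1 (2.10). They also held Fgfr3 (2.91), Cyp26b1, which breaks down retinoic acid (2.58), and Hand1 (2.35). Myh6 and Myh7 are close relatives, Hoxa3 spans Hoxa4 and Hoxa5, and Hoxd3 spans Hoxd4, so their shares of reads are uncertain. Actc1, Neurog2 and Wnt3a were under 2-fold apart with spike-in scaling. Replicate 1 held more of Aldh1a1 (3.60-fold), Runx2 (3.23), Myod1 (3.13), Krt15 (3.04), Osr2 (2.68), Pax1 (2.43), Fgf17 (2.38), Pmel (2.06), Hbb-bs (2.04), Nkx2-1 (2.03) and Tyr (2.03), besides Myog, Krt5 and Tnc. Tyr was under 2-fold apart by the TPM ratio when 0.1 was added to each TPM.

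**Figure D4:**
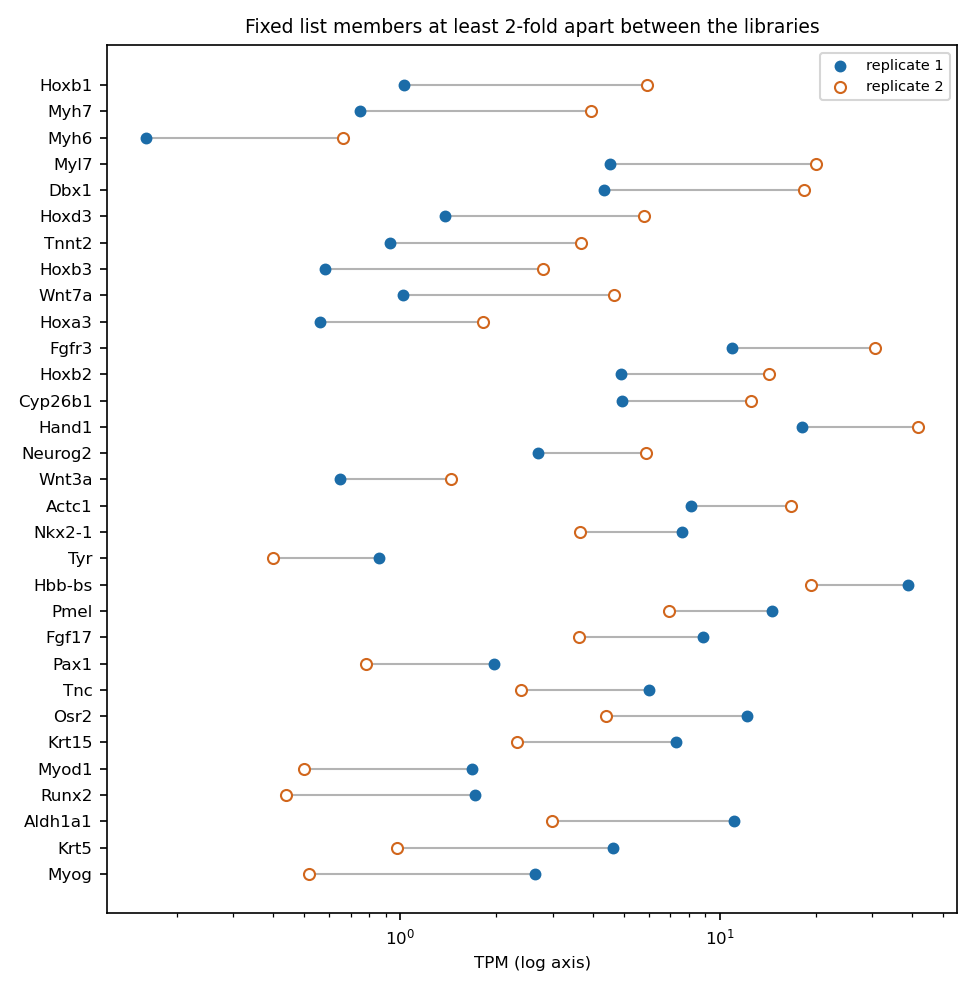
TPM (log axis) of 31 list members at least 2-fold apart in replicate 1 (filled circles) and replicate 2 (open circles), ordered by the ratio of their scaled counts. The 17 genes at the top, from Hoxb1 to Actc1, were higher in replicate 2.

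As groups and with TMM scaling, 17 of the 33 lists had a median ratio outside the central 95% of matched random lists, where chance gives 1.65. In replicate 2, 7 were higher. The heart list led with a median log2 ratio of 1.32 (8 of 10 members higher, 4 of them 2-fold), followed by Hox genes at 1.01 (21 of 22) and neural tube progenitors at 0.71 (9 of 10), among them Hes5 at 0.82. The Hox median fell on Hoxc10 and Hoxd10, each with 0 counts in replicate 1 and 2 in replicate 2, so its size is uncertain. Among members with a mean count of at least 50, 5 of 6 Hox genes were at least 2-fold higher in replicate 2. For heart genes the number was 4 of 5. Smaller shifts were seen for sex-linked genes at 0.29 (4 of 6), embryonic growth regulators at 0.20 (9 of 10, Sall4 at 0.57), hypoxia and glycolysis at 0.16 (9 of 11) and neurons and cranial ganglia at 0.14 (9 of 13). With spike-in scaling the medians of the last 3 of these lists were below 0, the lowest at -0.07, so these lists were higher in replicate 2 only relative to other genes.

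In replicate 1, 10 lists were higher. Eye and pigment genes had a median of -0.56 (0 of 10 higher in replicate 2), pharyngeal endoderm -0.46 (3 of 10) and macrophage genes -0.40 (0 of 12, Lyz2 at -0.71). The Dlx family at -0.21 (0 of 6), frontonasal and maxillary regulators at -0.21 (3 of 15, Alx1 at -0.70) and extracellular matrix at -0.21 (1 of 18, Lum at -0.81) followed. The erythroid list stood at -0.18 (4 of 13, Hbb-bt at -0.98), the mandibular list at -0.17 (4 of 12), the retinoic acid list at -0.15 (6 of 14, Rarb at -0.64) and the mesenchyme regulators at -0.05 (10 of 25). The erythroid and mandibular lists, higher in replicate 1 by their median ratio, had the larger median TPM in replicate 2, and neurons, neural tube progenitors and embryonic growth regulators showed the converse, since each median falls on different members. Hox and heart genes sat at low counts, with 6 of 22 measured Hox genes and 5 of 10 heart genes at a mean count of at least 50.

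**Figure D5:**
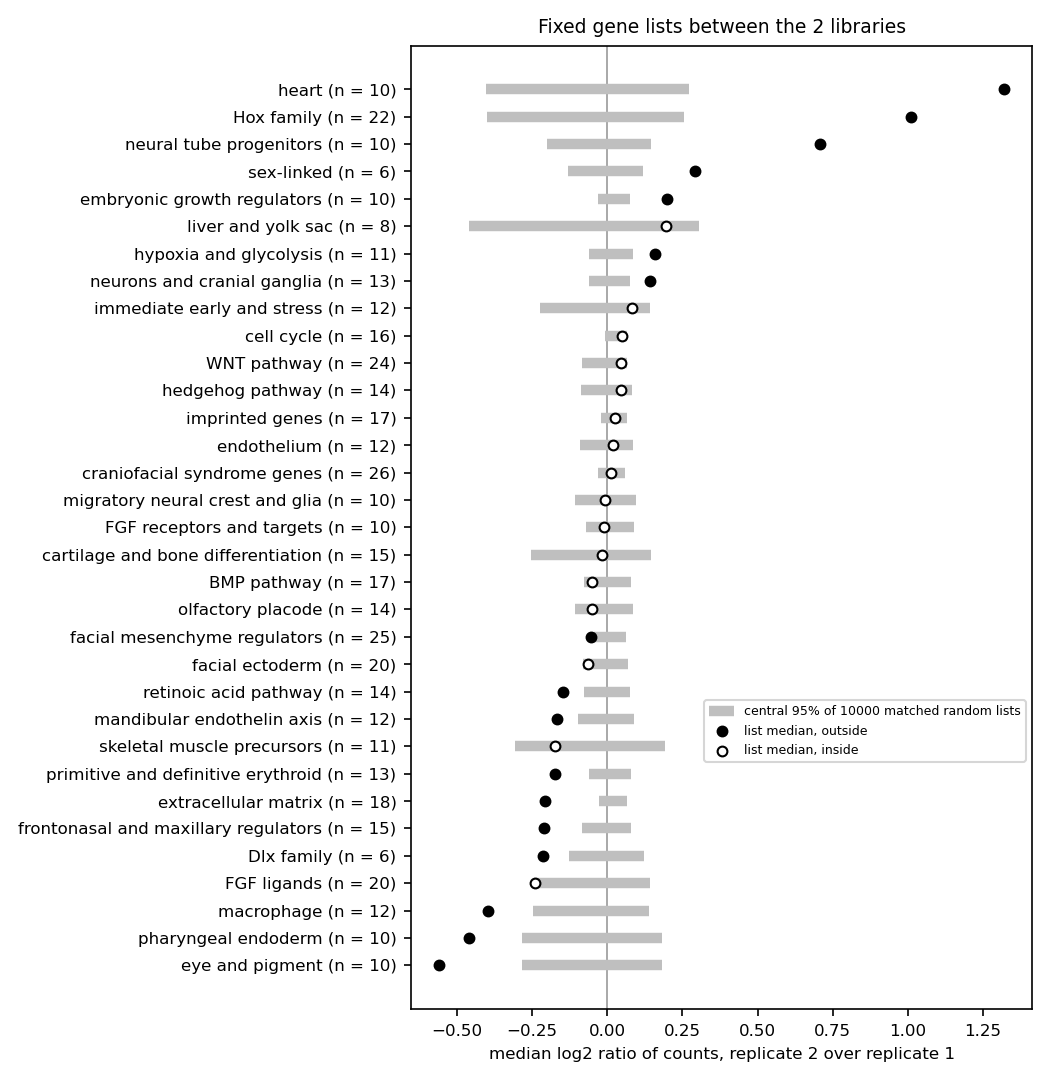
Median log2 ratio of counts, replicate 2 over replicate 1, of 33 gene lists (circles; filled where outside), with grey bars for the central 95% of 10000 random lists of the same size matched on expression; n is the number of members measured. The heart list lies at 1.32 and the eye and pigment list at -0.56.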

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

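Counts appeared among the 26248 short entries with numeric identifiers, which no comparison used. They came to 66.46 expected counts over 9 entries in replicate 1 and to 60 over 6 entries in replicate 2, that is 1.60 and 1.46 per 1000000 counts, above the limit of 3 counts per library that a count of 0 allows (0.072 and 0.073 on the same scale). A single entry held 40 and 35 of these counts. In both libraries 26185 of the entries had an effective length of 0 bases, so nearly all of them could not receive counts. No explanation was tested.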

How the results depend on the processing

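The limits to protein coding genes and to an effective length of at least 100 bases, and the list medians with spike-in scaling, were chosen after seeing the data. Without a count filter 2390 genes were at least 2-fold apart (1200 higher and 1190 lower in replicate 2), and with a mean count of at least 200 there were 58 (29 and 29). These settings test more or fewer genes by construction. Spike-in scaling gave 49 higher and 187 lower genes. Pearson's r was 0.970 with a pseudocount of 0.1, and Spearman's rho was 0.964 with no filter. Isoform agreement was 91.0% from a mean TPM of at least 1 and 95.6% from at least 20. Spike-in controls made up 8.43% of TPM, against 3.70% of counts, and 3.46% to 3.94% of counts without each replicate in turn. The cause was not tested for the correlations, the isoforms or the spike-in share. Without each replicate in turn, genes detected came to 14548 to 14725, 29 to 31 lists had at least 50% of members detected, and 35 pairs differed by more than the spread in both cases.

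All 33 lists kept their side of the central 95% with a prior count of 0.5 and a mean count of at least 50. Another scaling moves a list and its random lists alike, so it does not test this call. Of the 17 lists outside, 14 medians kept their sign with spike-in scaling, and 3 changed it: embryonic growth regulators (-0.015), hypoxia and glycolysis (-0.055) and neurons and cranial ganglia (-0.072). Of 39 pairs, 39 kept their call with a pseudocount of 1 and 37 with posterior mean TPM, where Meis2 over Meis1 (-0.15) lost it and Bmp4 over Bmp7 (0.24) gained it. Xist over Ddx3y (0.55) gained it without replicate 2. Of 47 named ratios, 47 stayed at least 2-fold under DESeq2 size factors and total count, 46 by the TPM ratio with 0.1 added, and 44 with spike-in scaling and with posterior mean counts. Of 212 gene levels, 151 moved by more than 1 SD when TPM was rescaled over protein coding genes and 47 with posterior mean TPM. No called pair and no named ratio reversed.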

Other observations

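The test of library noise was chosen after the result was seen. The second lists were written down before their values were looked at, and none of their genes stood in a first list. Glycolytic enzyme genes were abundant, with 9 of 9 detected and a median of 298 TPM. Gapdh stood at 2389 ± 113 TPM (SD, n = 2), Pgam1 at 854 ± 62.6 and the lactate transporter gene Slc16a3 at 131 ± 29.2. Connective tissue genes had 11 of 14 detected (median 4.76 TPM), led by the microfibril gene Mfap4 at 119 ± 26.8, Cthrc1 at 55.4 ± 4.78 and the growth factor gene Igf1 at 36.3 ± 6.75. Muscle differentiation genes were low (3 of 10 detected, median 0.32), with the myosin light chain gene Mylpf highest at 7.12 ± 0.389. Epidermal differentiation genes had 4 of 11 detected (median 0.405), where the basal integrin gene Itga6 (28.3 ± 0.0850) and Sfn (26.6 ± 5.0) stood far above the keratin gene Krt17 (0.405 ± 0.233). Forebrain and midbrain genes had 8 of 11 detected (median 1.75), led by Six3 at 9.20 ± 2.63.

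Globin genes differed unequally between the pools. Hbb-bt had 267 TPM in replicate 1 and 133 in replicate 2, and Hbb-bs had 38.8 and 19.3. The log2 ratios of the definitive Hba-a1 and Hba-a2 were -0.24 and -0.27, close to those of the embryonic Hbb-y (-0.21) and Hba-x (-0.14), and that of the embryonic Hbb-bh1 was 0.09. Hbb-bs and Hbb-bt are near-identical, and no difference between globin types was tested. In the eye and pigment list, the lens crystallin gene Cryaa had 0.66 TPM in replicate 1 and 0 in replicate 2, and Crybb1 had 0.67 and 0.16. Afp, a yolk sac and liver gene, had 0.11 TPM in replicate 1 and 1.09 in replicate 2, and Alb had none in either.

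Hindbrain and heart genes were higher in replicate 2, and hindbrain or heart tissue in that pool's dissection is a candidate explanation: the median log2 ratio of the second list was 0.719 for hindbrain (17 of 18 higher; random lists -0.225 to 0.123) and 0.588 for heart (13 of 16 higher; -0.325 to 0.204). Library noise was argued against by both second lists (2 of 2) lying above the range of random lists matched on counts. That test was set after the result was seen and rests on the same 2 medians, so it adds no support beyond them. GC content or length bias was argued against by its weak trend over 14035 genes, with Spearman rho 0.062 for GC content and 0.01 for length. The correction was at most 0.029 in log2. The 10 Hox, neural tube and heart members at least 2-fold apart had absolute log2 ratios of 1.519 or more. That 10 of 10 stayed 2-fold apart therefore followed from the size of the correction and is no added support. A rise of forebrain and midbrain genes as large as that of the hindbrain list was argued against by their second list, whose median was 0.099 (6 of 11 higher, random lists -0.308 to 0.194). A smaller rise of all neural tissue stays open. The lists of neurons and cranial ganglia (0.142) and of neural tube progenitors (0.708) lay above their ranges, and a median of 0.142 would have stayed within the forebrain and midbrain range. The most abundant second-list genes were, for hindbrain, Gata3 (20.6 and 24.3 TPM) and Irx3 (17.2 and 17.8) and, for heart, Tnni1 (4.61 and 6.57) and Tnnc1 (2.51 and 5.15), and 10 of 18 hindbrain and 4 of 16 heart genes had a TPM of at least 1 in replicate 1, so this tissue also held RNA of those genes. Against heart tissue stand Nppa (0.17 and 0.09 TPM), Nkx2-5 (0.64 and 0.40) and Sln (0.54 and 0), all at low counts; beyond the tissue dissected, no biological explanation was tested, since the design has 1 group.

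Extracellular matrix genes and single keratin and muscle genes such as Krt5 and Myog were lower in replicate 2, while the facial ectoderm list (-0.065) and the skeletal muscle list (-0.174) lay within their ranges and Actc1 was 2-fold higher there; embryos of replicate 1 being older on average may account for part of it. Of 4 second lists, 2 lay on the side this age difference needs, connective tissue at -0.454 (3 of 14 higher; random lists -0.150 to 0.096) and glycolysis at 0.133 (8 of 9 higher; -0.038 to 0.083). Muscle differentiation at -0.205 (-0.539 to 0.378) and epidermal differentiation at -0.056 (-0.306 to 0.205) lay within their ranges, so the explanation stays open. The first lists of matrix (-0.207) and of hypoxia and glycolysis (0.159) had already lain on those sides in these libraries, the latter at -0.055 with spike-in scaling. The second lists therefore repeat the pattern and cannot tell an age difference from another cause. For the matrix list GC content or length bias was argued against by the size of the correction, at most 0.029 in log2. Its median was -0.207 before and -0.218 after the correction. That all 3 of the 3 lists tested (with macrophage and embryonic growth regulators) stayed outside followed from this size and is no added support. Keratin and muscle genes were not part of that test. Besides age, no biological explanation was looked at.

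Xist, expressed from the inactive X chromosome, stood at 20.3 TPM in replicate 1 and 13.4 in replicate 2, while the Y-linked genes Eif2s3y, Uty, Kdm5d and Ddx3y had log2 ratios of 0.50, 0.35, 0.35 and 0.23 in favor of replicate 2. A larger share of male embryos in replicate 2 is a candidate explanation, and the labels say only that sexes were pooled. It remained open, because 0 of 5 genes of the second Y-linked list (Usp9y, Zfy1, Zfy2, Sry and Uba1y) had counts in either library. A list without counts cannot test the share of male embryos. Uty had 876 and 1088 counts, but whether this tissue expresses the 5 listed genes at all was not tested. No biological explanation was tested.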
